A study of Homo sapiens with 39 samples.

How the data were processed

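Gene expression was measured in U937, an established human histiocytic lymphoma cell line, on Affymetrix 3' IVT arrays. Per the labels' protocols, exponentially growing cells were cultured with 10 µM of 1 of 3 oligonucleotides (Pu27, Pu9- or Pu5-) or without treatment, and cells were collected at 24, 48 and 72 h, with untreated cells also collected at 0 h. The labels describe pellets kept in TRIzol until the samples of 3 repeat experiments had been collected, and biotinylated cRNA made from 100 ng of total RNA. There were 39 arrays in 13 groups of 3. The labels detail the repeats no further, so the p-values measure the spread between these samples.

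The deposited values are in log2 units: per the submitters' processing notes, the authors used RMA, which corrects background, normalises quantiles over the arrays and summarises the probes of each probe set. The notes also name limma. Versions and settings of both are not given in the sources used here. One deposited table held 49495 probe sets with controls and the other 49395, the difference being 100 ERCC spike-in probe sets, and the largest difference between their shared values was 0. Each of the 39 columns was matched to a sample by its title. RMA compresses the differences between dim probe sets and makes the distributions of all arrays alike, so a change in the total RNA per cell is not measured.

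After the control probe sets were set aside, 49293 probe sets remained, of which 44988 were paired with a single gene symbol in the probe table. The 1832 probe sets paired with several symbols and the 2473 without a symbol were left out of the gene-level values. For each of 18132 genes the probe set with the highest mean over the 39 arrays was used; 11734 genes had more than 1 probe set. No filter on dim genes was applied. Genomic positions were not used, and no probe set was called present or absent.

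Differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model that held a mean for each of the 13 groups and the default empirical Bayes prior (26 residual and 7.13 prior degrees of freedom). Each oligonucleotide was compared with untreated cells of the same time, and as the mean of the 3 time-matched differences. The oligonucleotides were compared with each other in the same way, and untreated cells at each later time were compared with 0 h. A moderated F test asked for each oligonucleotide whether its effect differed between the 3 times. Adjusted p-values are Benjamini-Hochberg values over all genes within a contrast, with a threshold of 0.05. Values after ± signs are standard errors of limma's estimates unless an SD is named, with 3 arrays per group at a single time and 9 per arm for a mean over times.

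A total of 29 gene lists with 574 entries, 521 of them measured, was drawn up from general knowledge: MYC target genes, cell cycle genes, p53 target genes, apoptosis regulators, type I interferon response, NF-kB and inflammatory genes, nucleic acid sensing, monocyte and macrophage markers, granule enzymes of immature myeloid cells, unfolded protein and integrated stress response, heat shock proteins, NRF2 targets, metallothioneins, sterol and fatty acid synthesis, hypoxia and glycolysis, immediate early and MAPK response, ribosomal proteins, oxidative phosphorylation, DNA repair and damage response, G-quadruplex helicases and binding proteins, genes with a G-quadruplex motif described in their promoter, autophagy and lysosome, scavenger and uptake receptors, polyadenylated histone genes, and markers of T, B, erythroid, epithelial and fibroblast cells. Each list was tested with limma's camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, with adjustment over the lists within a contrast. Unless said otherwise, the p-value printed for a list is camera's with the preset correlation. Member counts are given over all genes and adjusted over the list alone.

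The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took MYC always; for each mean contrast against untreated cells, the 10 largest rises and 10 largest falls that passed the test, had the same sign at all 3 times and a mean log2 of at least 6 in the higher arm; for each single time, the 2 largest in each direction with every treated array beyond every untreated array; for untreated cells at 72 h against 0 h, the 10 largest in each direction by the same rule; for each pair of oligonucleotides, the 5 largest in each direction over the mean of the times; for each F test, the 3 genes with the smallest adjusted p; and for each list, the 4 members with the largest absolute mean change. Other genes named, among them every gene of a small count, list members singled out for a single time and the 3 lists of selenoproteins, G1/S genes and G2/M genes, were chosen after their values were seen. Y-linked genes and XIST were left out of the named genes. No other probe set of a named gene passed the test with the opposite sign.

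The alternatives were a filter keeping the 13131 genes with a group mean log2 of 5 or more, the mean of a gene's probe sets, every probe set tested on its own, an intensity trend with a robust prior, arrays shifted to a common median, a fit of the compared groups only, the replicate number as a block, and leaving out each array and each replicate number in turn. Added after seeing the data were the ACTB 3' minus 5' signal difference as a covariate and the mean contrasts without 72 h. Same-numbered replicates were checked for pairing through the correlation of their deviations from the group means. For 8 of the 12 contrasts of an oligonucleotide with untreated cells every such correlation was over 0.1 (up to 0.53 for Pu27 at 48 h), so blocked values are given where they change a result. Correlations between effects that share untreated arrays were set beside 50 simulations of unchanged groups, and overlaps of calls beside 200, added after seeing the data, which took from unchanged groups lists as long as the observed ones. The fits were tested on simulated data with 200 changed genes: for Pu27 at 72 h, all genes changed by 1 on the log2 scale and 56% of those changed by 0.5 were recovered, with 12 false calls among 168. With no gene changed, 0 genes were called in 2 single-time contrasts and 3 in the mean contrast of Pu27. This is not the false-call rate on the real arrays, where other splits (below) gave up to 414 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Few arrays limit precision: at single times the median interval of a log2 difference between oligonucleotides reached 0.244 to either side.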

Results

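The series asks how 3 G-rich oligonucleotides, homologous to a G-quadruplex-forming element of the MYC promoter (NHEIII1), affect leukemia cell growth and MYC expression. The oligonucleotides were Pu27 (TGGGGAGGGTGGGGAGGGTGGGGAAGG, 27 nt with 20 guanines), Pu9- (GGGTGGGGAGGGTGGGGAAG, 20 nt with 15 guanines, the stretch from position 7 to 26 of Pu27 counted from its 5' end) and Pu5- (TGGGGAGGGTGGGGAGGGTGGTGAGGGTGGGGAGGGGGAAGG, 42 nt with 31 guanines, sharing a run of 21 nt with Pu27). U937 cells, a myeloid line with features of immature monocytes, received 10 µM of each for 24, 48 or 72 h, in 3 arrays per group. Untreated cells at 0, 24, 48 and 72 h were the controls, and the design held no control oligonucleotide of another sequence. Array medians lay between 5.82 and 5.94 on the log2 scale. The leading principal component held 57.9% of the variance and placed the 24 h and 72 h arrays at its ends, with the 0 h and 48 h arrays between them.

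MYC, the transcription factor whose promoter these sequences match, passed the test in none of the 12 comparisons of an oligonucleotide with untreated cells. With Pu27 its log2 change was -0.26 at 24 h (95% interval -0.47 to -0.05, adjusted p = 0.719), -0.02 at 48 h and -0.23 at 72 h (-0.44 to -0.01, adjusted p = 0.245), with a standard error of 0.11 each. The mean over the times was -0.17 ± 0.06 (-0.29 to -0.05, adjusted p = 0.129). MYC was named in advance, and its unadjusted p from limma was 0.019 at 24 h, 0.038 at 72 h and 0.0088 for the mean. A small fall of MYC with Pu27 is thus neither called over all genes nor excluded. The mean change was -0.04 ± 0.06 with Pu9- and -0.06 ± 0.06 with Pu5-. At matched times the mean difference of MYC between Pu27 and Pu9- was -0.13 ± 0.06 (-0.250 to -0.003, adjusted p = 0.404, unadjusted 0.045). Between Pu27 and Pu5- it was -0.11 ± 0.06 (-0.23 to 0.01, adjusted p = 0.567, unadjusted 0.081). Neither difference passed the test over all genes, and Pu9- and Pu5- differed by 0.02 ± 0.06. In untreated cells MYC fell with time in culture, from a mean log2 of 12.28 (SD 0.18, n = 3) at 0 h to 12.14 at 24 h, 11.93 at 48 h and 11.75 (SD 0.02) at 72 h. It fell by 0.53 ± 0.11 at 72 h (adjusted p = 0.00059) and by 0.35 ± 0.11 at 48 h (adjusted p = 0.042). The call at 48 h was lost without any of 4 arrays, untreated 0 h replicate 2 (adjusted p = 0.156) or 3 (0.173) and untreated 48 h replicate 2 (0.159) or 3 (0.140). It was also lost without all arrays of replicate 2 (0.540) or 3 (0.408), and in 4 settings that keep all arrays, with an adjusted p of 0.268 from a fit of the compared groups only, 0.053 over every probe set, 0.056 with arrays shifted to a common median and 0.069 with the ACTB covariate. The call at 72 h was lost without all arrays of replicate 2 (0.103).

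**Figure D1:**
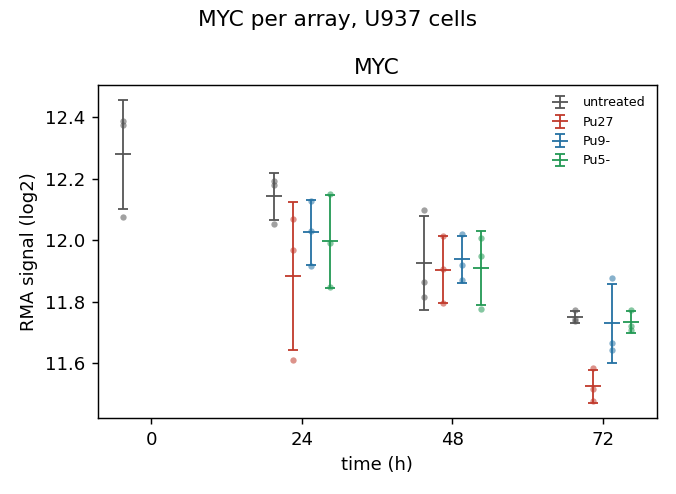
MYC signal (RMA, log2) against time in culture (h) for untreated cells and cells with each oligonucleotide; points are single arrays, dashes group means and bars the SD of 3 arrays. Untreated means fall from 12.28 at 0 h to 11.75 at 72 h, and Pu27 at 72 h has a mean of 11.52.

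Counts of genes past the threshold were small at 24 and 48 h and largest at 72 h for each oligonucleotide. Pu27 changed 12 genes at 24 h (8 higher, 4 lower), 35 at 48 h (19 and 16) and 922 at 72 h (533 and 389). Pu9- changed 3, 3 and 174 genes and Pu5- 3, 3 and 141 genes. For the mean of the times the counts were 722, 16 and 46. In a fit of the compared groups only, with fewer samples, they were 4, 2 and 335 for Pu27, 1, 0 and 0 for Pu9-, 3, 0 and 15 for Pu5-, and 682, 5 and 22 for the means. Few genes changed at least 2-fold: at 72 h 16 were higher and 7 lower with Pu27, 6 lower with Pu9-, and 2 higher and 3 lower with Pu5-.

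**Figure D2:**
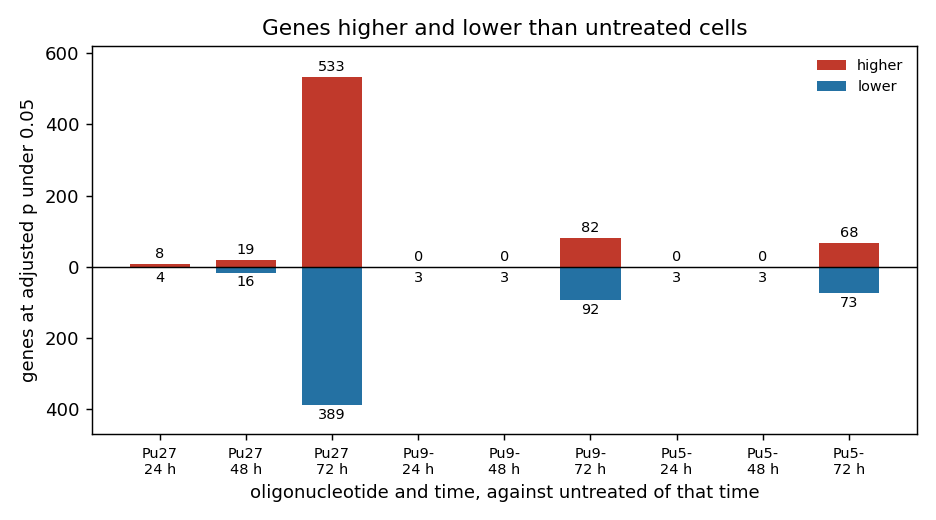
Number of genes at an adjusted p under 0.05 (vertical axis; red bars upward for genes higher, blue bars downward for genes lower than in untreated cells of the same time) for each oligonucleotide and time (horizontal axis). Pu27 at 72 h has 533 higher and 389 lower, against 82 and 92 with Pu9- and 68 and 73 with Pu5-.

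The same 3 genes fell with all 3 oligonucleotides at 24 and 48 h, and all 3 encode selenoproteins: SELENOW and SELENOH, small thioredoxin-like proteins, and GPX1, the cytosolic glutathione peroxidase. At 24 h SELENOW fell by 1.23 with Pu27 (adjusted p = 9.8e-11), 1.38 with Pu9- (3.5e-12) and 1.31 with Pu5- (1.7e-11), each ± 0.09 on the log2 scale. At that time GPX1 fell by 0.74, 0.66 and 0.91, and SELENOH fell by 0.67, 0.62 and 0.80, in the same order. At 48 h SELENOW fell by 0.57, 0.66 and 0.77, GPX1 by 0.68, 0.79 and 0.91, and SELENOH by 0.56, 0.59 and 0.71. Each of these 18 changes had an adjusted p of 0.00084 or less. In a fit of the compared groups only, with fewer samples, 5 of the 18 calls held, SELENOW at 24 h with each oligonucleotide (up to 0.0024) and SELENOH (0.037) and GPX1 (0.045) at 24 h with Pu5-. The 13 others ended (0.059 to 0.29), among them all at 48 h, whereas the 9 mean changes held in that fit (up to 3.2e-05, for GPX1 with Pu27). These were the only genes called with Pu9- and with Pu5- at either time. In simulations of unchanged groups sharing the untreated arrays, lists of falls as long as these had on average 0.010 genes in common to all 3 at 24 h and 0.035 at 48 h (highest 1). At 72 h SELENOH fell by 0.40 with Pu27, 0.42 with Pu9- and 0.46 with Pu5-. SELENOW passed the test with Pu27 (-0.41) and Pu5- (-0.36, adjusted p = 0.0499) and GPX1 with Pu5- (-0.43, adjusted p = 0.021). In untreated cells SELENOW stood at 6.63, 7.70, 6.96 and 6.57 at 0, 24, 48 and 72 h, and in treated cells between 6.15 and 6.47. Other probe sets of GPX1 and SELENOH gave mean changes from -0.53 to -0.79. Of 24 measured selenoprotein genes, 20 passed the test in none of the 3 mean contrasts. Besides the 3 named above, SELENOS, a protein of the endoplasmic reticulum, rose by 0.21 with Pu27 (adjusted p = 0.0043). The mean change of SELENOW differed by 0.06 between Pu27 and Pu9- (-0.05 to 0.16), by 0.08 between Pu27 and Pu5- (-0.03 to 0.18) and by 0.02 between Pu9- and Pu5- (-0.09 to 0.13). GPX1 was 0.20 higher with Pu27 than with Pu5- (0.09 to 0.31, adjusted p = 0.125). Without all arrays of replicate 2 the count for Pu9- at 24 h was 1, and at 48 h it was 1 without replicate 3 and 7 without replicate 1.

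**Figure D3:**
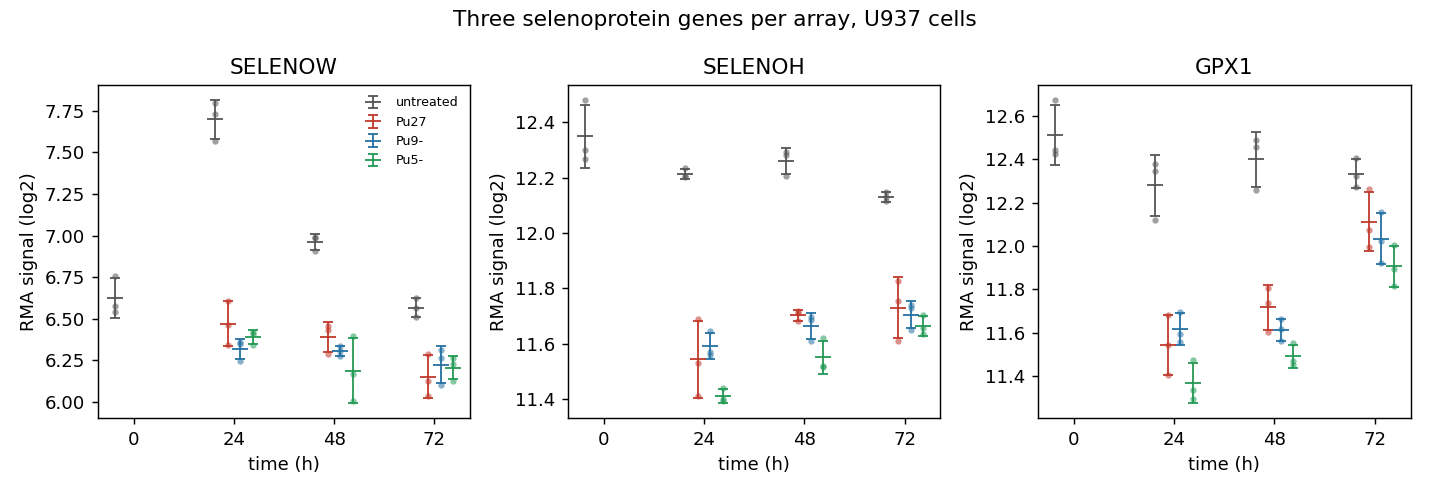
Signal (RMA, log2) of SELENOW, SELENOH and GPX1 against time in culture (h), with points for single arrays, dashes for group means and bars for the SD of 3 arrays. SELENOW of untreated cells peaks at 7.70 at 24 h while the treated groups stay between 6.15 and 6.47.

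At 24 h Pu27 raised 8 genes. The largest rises were in AIM2, a sensor of cytosolic double-stranded DNA (1.25 ± 0.26, adjusted p = 0.043), CMPK2, an interferon-induced nucleotide kinase (0.92 ± 0.18, 0.032), and ITGAM, the CD11b integrin chain of myeloid cells (0.88 ± 0.17, 0.019). Other probe sets of CMPK2 did not rise (-0.18 and -0.07), so its rise rests on the probe set used. ATP10D, RIT1, OPTN and ORC3 rose by 0.45 to 0.78. The chemokine CXCL11 also passed upward, but in untreated cells it lay at the level of the background probes (3.26, against 3.06 to 3.25), so no size is given. CDC20, an activator of the anaphase-promoting complex, fell by 0.42 beside the 3 selenoprotein genes. Among the type I interferon genes 19 of 29 were higher (median 0.13, adjusted p = 0.00031, and 0.015 with an estimated correlation), with CMPK2 the single member past the test over all genes and adjusted over the list alone. MYC target genes were lower in 32 of 38 (median -0.12, adjusted p = 8.0e-05). None of them passed over all genes and 1 fell adjusted over the list alone, and the adjusted p was 0.16 with an estimated correlation. NF-kB genes (18 of 23 higher, median 0.12, adjusted p = 0.0013) and DNA repair genes (13 of 16 higher, median 0.07, 0.016) had no member past the test over all genes, and 1 and 0 rose adjusted over each list alone. Their adjusted p was 0.37 and 0.43 with an estimated correlation. The G1/S and G2/M genes are parts of the cell cycle list set apart after the values were seen. Their p-values, adjusted over 3 such lists only, therefore describe them here and below and do not test them. Of 15 G1/S genes 12 were higher (median 0.14, 0 past the test, 3 adjusted over the list alone, adjusted p = 0.030 with an estimated correlation). Of 16 G2/M genes 13 were lower (median -0.06, 0.036), with CDC20 past the test and 1 adjusted over the list alone. With a replicate block the count was 37 in place of 12, and the lists of apoptosis regulators (adjusted p = 0.046), NRF2 targets (0.046) and sterol synthesis (0.012) also passed. The count was 5 and 3 without untreated 24 h replicate 1 or 3, and 4, 3 and 25 without Pu27 24 h replicate 1, 2 or 3. The call of AIM2 ended without 4 and that of CMPK2 without 5 of the 6 arrays in turn (adjusted p up to 0.54 and 0.30, without Pu27 24 h replicate 1). The interferon list lost its call in 1 (0.057) and the NF-kB list in 2 (up to 0.51), both without that same array. The DNA repair list lost it in 3 (up to 0.23 without Pu27 24 h replicate 2).

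At 48 h Pu27 raised CCNE2, which encodes cyclin E2 of the G1/S transition, by 1.12 ± 0.24 (adjusted p = 0.024), and CCDC80, a secreted matrix protein, by 1.12 ± 0.16 (0.00012). PIF1, a helicase that unwinds G-quadruplexes, fell by 0.92 ± 0.17 (0.0051) and SLC7A11, the cystine transporter, by 0.83 ± 0.14 (0.0015). Monocyte and macrophage markers were higher in 18 of 28 (median 0.06, adjusted p = 7.7e-05, and 0.21 with an estimated correlation). Over all genes 3 of them rose, ITGAM by 1.05, CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by 1.01 and HLA-DRA, an MHC class II chain, by 0.86, and 6 rose adjusted over the list alone. Of the 16 G2/M genes 15 were lower (median -0.24, adjusted p = 1.4e-06 with an estimated correlation). CDC20 (-0.59), CCNB1 (-0.43), which encodes cyclin B1, and the mitotic kinase AURKA (-0.32) passed the test, and 10 passed adjusted over the list alone. The G1/S genes were higher in 14 of 15 (median 0.14, adjusted p = 0.013 with an estimated correlation), with CCNE2 past the test and 5 adjusted over the list alone. Heat shock protein genes (11 of 14 higher, median 0.14, adjusted p = 0.0044) and sterol synthesis genes (17 of 19 higher, median 0.15, 0.00032) had no member past the test over all genes, and 1 and 0 rose adjusted over each list alone. Their adjusted p was 0.064 and 0.60 with an estimated correlation. With a replicate block the count was 80 in place of 35 and the interferon list also passed (adjusted p = 0.047). The count was 15 and 18 without untreated 48 h replicate 2 or 3, and 15 and 20 without Pu27 48 h replicate 1 or 2. The calls of CCNE2 and PIF1 ended without 5 and 3 of the 6 arrays in turn (adjusted p up to 0.34 and 0.18, without Pu27 48 h replicate 1).

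At 72 h with Pu27 CCNE2 rose 3.73-fold (1.90 ± 0.24, adjusted p = 4.5e-06), RRM2, a subunit of ribonucleotide reductase, by 1.06, CDC6, a replication licensing factor, by 1.02, the phosphatase CDC25A by 0.78 and the transcription factor E2F1 by 0.76. All 15 G1/S genes were higher (median 0.48, adjusted p = 0.00041 with an estimated correlation). Of them 13 passed the test over all genes, 14 adjusted over the list alone and 12 over all genes with the ACTB covariate described below. The G2/M part had a median of 0.07, with BIRC5 (0.30) past the test upward and CCNB1 (-0.35) downward. In the whole list of 31 cell cycle genes 14 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.36, adjusted p = 1.1e-10, and 0.015 with an estimated correlation). The ACTB 3' minus 5' signal difference, a sign of RNA quality, was 2.24 with Pu27 at 72 h and 2.05 in untreated cells at 72 h, a difference of 1.79 SD within groups, and that of GAPDH was 0.61 and 0.51 (0.972 SD). With the ACTB difference as a covariate, added after seeing the data, the count of 922 was 665.

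In the same cells, with the same ACTB difference, CCDC80 rose 3.43-fold (1.78 ± 0.16, adjusted p = 1.2e-08). The largest falls were in LOC105375218 (-1.57 ± 0.41, 0.019) and MINAR1 (-1.18 ± 0.17, 4.8e-05). Among monocyte and macrophage markers 22 of 28 were higher (median 0.22, adjusted p = 0.00045, and 0.18 with an estimated correlation). The gelatinase MMP9 rose by 1.42, HLA-DRA by 1.20, ITGAM by 0.94 and TYROBP, an adaptor of myeloid receptors, by 0.46, and 5 rose adjusted over the list alone. DNA repair genes moved both ways, with 7 higher and 2 lower of 16 past the test (8 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.00097, and 0.18 with an estimated correlation). The exonuclease EXO1 rose by 0.84, RAD54L by 0.64 and the checkpoint kinase CHEK1 by 0.47, whereas the kinases ATM (-0.47) and ATR (-0.42) fell. Of 38 MYC target genes 27 were lower (median -0.14, adjusted p = 9.9e-05, and 0.18 with an estimated correlation). The ribosome biogenesis factors MRTO4 (-0.49) and RRS1 (-0.44) and IMPDH2 of guanine nucleotide synthesis (-0.39) fell and SHMT1 rose (0.31). There were 1 rise and 5 falls adjusted over the list alone. All 19 sterol synthesis genes were higher (median 0.28, adjusted p = 0.00030, and 0.38 with an estimated correlation), with FDPS (0.41) and ACAT2 (0.46) past the test and 5 adjusted over the list alone. NF-kB genes had a median of 0.15 (adjusted p = 0.012, and 0.38 with an estimated correlation). The cytokine IL1B (1.01), PLAUR, the urokinase receptor (0.82), and the chemokine CCL3 (0.70) passed the test, also 3 adjusted over the list alone. Genes of the unfolded protein and integrated stress response had a median of 0.18 (adjusted p = 0.043, and 0.38 with an estimated correlation). PDIA4 (0.40) and CRELD2 (0.37) passed the test over all genes and 2 adjusted over the list alone. The count of 922 was 568 and 513 without untreated 72 h replicate 1 or 2, 613 without Pu27 72 h replicate 2, and 68 without all arrays of replicate 2. The stress response call and that of LOC105375218 each ended without 4 of the 6 arrays in turn (adjusted p up to 0.088 without Pu27 72 h replicate 3 and 0.078 without untreated 72 h replicate 1).

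Over the mean of the times, Pu27 raised 506 genes and lowered 216. CCNE2 rose 2.52-fold (1.33 ± 0.14, adjusted p = 7.7e-08), CCDC80 2.2-fold (1.14 ± 0.09, 2.5e-10) and ITGAM 1.94-fold (0.96 ± 0.10, 5.2e-08). RNASE6, an antimicrobial ribonuclease, rose by 0.98, the monocyte chemokine CCL2 by 0.95, MMP9 by 0.94, the receptor CD160 by 0.92, GPR18 by 0.83, the neutrophil chemokine CXCL8 by 0.82 and the fractalkine receptor CX3CR1 by 0.81. The largest falls were in LOC105375218 (-0.86), SELENOW (-0.74), PIF1 (-0.58), the lectin-like receptor CLEC12B (-0.57), the mitotic kinesin KIF20A (-0.55), GPX1 (-0.55), SELENOH (-0.54), PPP1R10 (-0.48), C6orf120 (-0.47) and SLC7A11 (-0.47). Of these 20 calls 4 ended without 1 of the 18 arrays. That of CCL2 ended in 10 such settings and that of CXCL8 in 4 (adjusted p up to 0.12 and 0.071, without Pu27 48 h replicate 1). That of LOC105375218 ended in 11 (0.107 without Pu27 24 h replicate 1) and that of PPP1R10 in 10 (0.093 without untreated 48 h replicate 3). The count of 722 was 114 without all arrays of replicate 2 and 207 without those of replicate 3. It was 78 without the 72 h arrays, a setting added after seeing the data.

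Of the gene lists, 7 passed for the mean effect of Pu27. Among cell cycle genes 11 rose and 2 fell (13 and 5 adjusted over the list alone; adjusted p = 0.0012, and 0.19 with an estimated correlation). The rises were led by CCNE2, RRM2 (0.67), CDC6 (0.58) and CCNE1 (0.52), which encodes cyclin E1, while CDC20 (-0.38) and CCNB1 (-0.34) fell. Monocyte and macrophage markers had 6 rises (8 adjusted over the list alone; adjusted p = 2.4e-05, and 0.095 with an estimated correlation), with ITGAM, MMP9, HLA-DRA (0.70) and CYBB (0.49) the largest. NF-kB genes had 6 rises (7 adjusted over the list alone; adjusted p = 0.00013, and 0.16 with an estimated correlation), CCL2, CXCL8, IL1B (0.61) and PLAUR (0.54) among them. Interferon genes had 4 rises (7 adjusted over the list alone; adjusted p = 0.0019, and 0.090 with an estimated correlation): CMPK2 (0.61), IFITM1 (0.29), IFI6 (0.25) and IRF7 (0.20). Sterol synthesis genes had 3 rises (6 adjusted over the list alone; adjusted p = 5.2e-06, and 0.26 with an estimated correlation), with HMGCS1, an enzyme of the mevalonate pathway, highest at 0.56. DNA repair genes had 6 rises (7 adjusted over the list alone; adjusted p = 8.0e-05, and 0.095 with an estimated correlation), among them EXO1 (0.48), RAD54L (0.30) and BRCA1 (0.26). MYC target genes were lower in 31 of 38 (adjusted p = 2.4e-05, and 0.095 with an estimated correlation). Past the test were falls of IMPDH2 (-0.34) and RRS1 (-0.27) and a rise of SHMT1 (0.19), with 1 rise and 3 falls adjusted over the list alone.

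**Figure D4:**
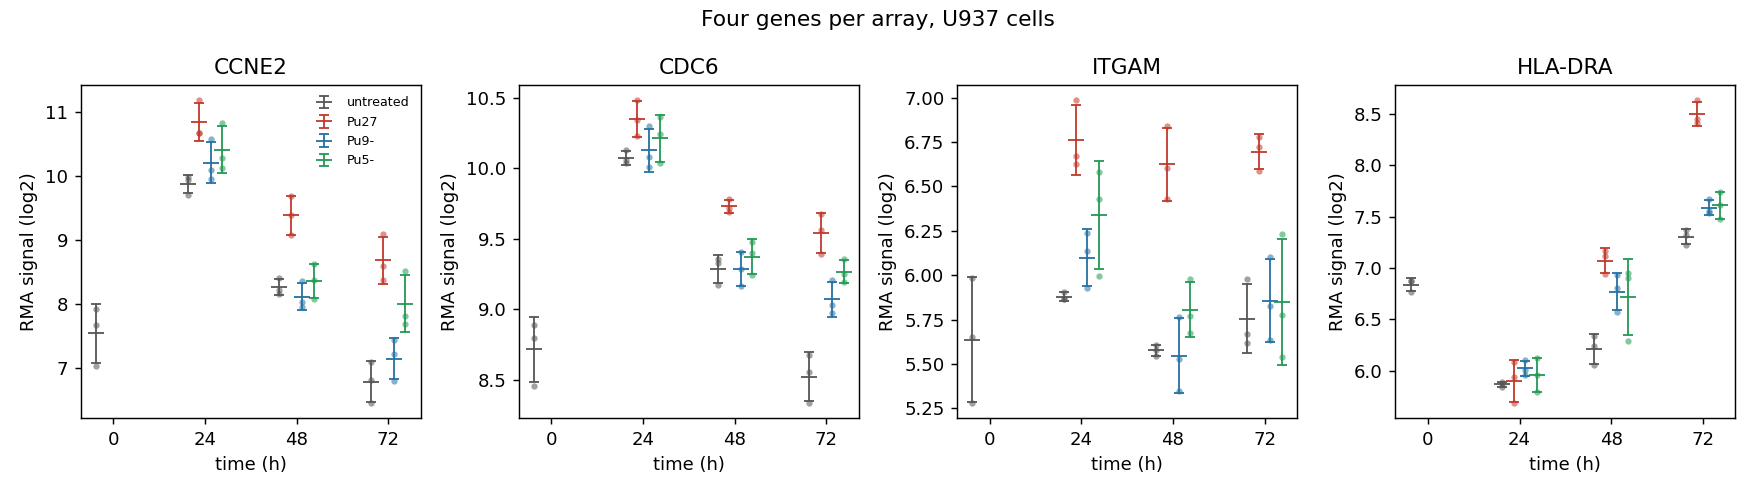
Signal (RMA, log2) of CCNE2, CDC6, ITGAM and HLA-DRA against time in culture (h); points are single arrays, dashes group means and bars the SD of 3 arrays. At 72 h HLA-DRA stands at 8.50 with Pu27 against 7.30 in untreated cells, 7.59 with Pu9- and 7.61 with Pu5-.

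Pu9-, the shortest of the oligonucleotides, changed 174 genes at 72 h (82 higher, 92 lower) beyond the selenoprotein genes of the earlier times. The largest rises by the rule were PANK3, a pantothenate kinase of coenzyme A synthesis (0.97 ± 0.23, adjusted p = 0.027), and DOT1L, a histone H3 methyltransferase (0.95 ± 0.19, 0.011). The largest falls were LOC105375218 (-1.68 ± 0.41, 0.036) and WBP2NL (-1.38 ± 0.21, 0.00095). Cell cycle genes were higher in 25 of 31 (median 0.15, adjusted p = 2.0e-05, and 0.22 with an estimated correlation). CDC6 (0.55) and CDC25A (0.54) rose, and 3 rose adjusted over the list alone. All 19 sterol synthesis genes were higher (median 0.23, adjusted p = 4.0e-05, and 0.45 with an estimated correlation), none past the test over all genes or adjusted over the list alone. The zinc exporter SLC30A1 rose by 0.78, the single member past the test in the metallothionein list by either count (adjusted p = 0.027, and 0.33 with an estimated correlation). The stress response list (median 0.15, adjusted p = 0.0021) and the hypoxia and glycolysis list (median 0.11, 0.027) had no member past the test over all genes and 1 each adjusted over the list alone. Their adjusted p was 0.22 and 0.54 with an estimated correlation. With a replicate block the count was 459. In the fit of the compared groups only it was 0, so every gene call named here ended, and another split of the same 6 arrays gave 211 genes. The count was 64 and 23 without untreated 72 h replicate 1 or 3 and 1200, 4 and 16 without Pu9- 72 h replicate 1, 2 or 3. Without 1 array or another the calls of DOT1L, PANK3, LOC105375218 and the metallothionein list ended (adjusted p up to 0.23, 0.39, 0.42 and 0.12, each without Pu9- 72 h replicate 2), as did that of the hypoxia list (0.073 without untreated 72 h replicate 2).

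Over the mean of the times Pu9- raised 3 genes and lowered 13. Blocked by replicate it raised 35 and lowered 23, so the balance of rises and falls depends on the block. The rises were in GPD2, the mitochondrial glycerol phosphate dehydrogenase (0.32 ± 0.06, adjusted p = 0.034), PRPS1, which makes the ribose phosphate of nucleotide synthesis (0.30 ± 0.05, 0.0099), and LETM1 of the inner mitochondrial membrane (0.24 ± 0.05, 0.034). Besides SELENOW (-0.79), GPX1 (-0.58) and SELENOH (-0.55), the falls by the rule were CACNA2D4 (-0.62), AFF2 (-0.46), SLC7A11 (-0.39), CYP4V2 (-0.35), ATP8B4 (-0.35), ZKSCAN5 (-0.30) and CD38 (-0.26). Sterol synthesis genes were higher in 19 of 19 (median 0.13, adjusted p = 5.6e-06, and 0.43 with an estimated correlation), with HMGCS1 at 0.49 and IDI1 at 0.33, neither past the test. Cell cycle genes (24 of 31 higher, median 0.07, adjusted p = 5.4e-05) and heat shock protein genes (10 of 14 higher, median 0.08, 0.013) had no member past the test over all genes. Their adjusted p was 0.20 and 0.13 with an estimated correlation. Adjusted over the list alone, 1 member of each of these 3 lists rose. At 24 h the cell cycle list passed with no member past the test (median 0.08, adjusted p = 0.033, and 0.49 with an estimated correlation, 0.14 without untreated 24 h replicate 2). At 48 h heat shock protein genes (12 of 14 higher, median 0.11, adjusted p = 0.0029, and 0.038 with an estimated correlation, 0.15 without Pu9- 48 h replicate 1) and sterol synthesis genes (16 of 19 higher, median 0.10, 0.00073, and 0.84 with an estimated correlation) passed, with no member past the test by either count. Among the 13 named calls of the mean contrast, 9 ended without 1 array or another, and those of SELENOW, GPX1, SELENOH and CACNA2D4 held without each of the 18 arrays. The count of 16 moved to 4, 10 and 6 without untreated 24 h replicate 1, 2 or 3, to 9 and 6 without untreated 48 h replicate 1 or 3, and to 9 and 6 without untreated 72 h replicate 1 or 3. It moved to 6 without Pu9- 24 h replicate 1 or 3, to 4 and 7 without Pu9- 48 h replicate 2 or 3, to 226, 5 and 7 without Pu9- 72 h replicate 1, 2 or 3, and to 3 without all 72 h arrays.

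Pu5-, the longest of the oligonucleotides, changed 141 genes at 72 h (68 higher, 73 lower). CCNE2 rose by 1.22 ± 0.24 (adjusted p = 0.0065) and CCDC80 by 1.04 ± 0.16 (0.00034). The largest falls were PPP1R10, a regulatory subunit of protein phosphatase 1 (-1.05 ± 0.23, 0.021), and CACNA2D4 (-1.01 ± 0.19, 0.0038). All 15 G1/S genes were higher (median 0.36, adjusted p = 0.00015 with an estimated correlation). CCNE2, E2F1 (0.80), CDC6 (0.75), CDC25A (0.67) and CDC45 (0.54) passed the test, and 13 adjusted over the list alone. Of 16 G2/M genes 14 were lower (median -0.19, adjusted p = 0.00015 with an estimated correlation). CCNB1 (-0.55), TOP2A (-0.32) and CDC20 (-0.32) passed the test, and 5 adjusted over the list alone. The sterol synthesis list was higher in 19 of 19 (median 0.33, adjusted p = 2.8e-10, and 0.21 with an estimated correlation), with FDPS (0.48) past the test and 4 adjusted over the list alone. Single members rose in the p53 list (AEN, 0.37; 2 adjusted over the list alone; adjusted p = 0.0054, and 0.056 with an estimated correlation), the stress response list (TRIB3, 0.43; also 1 adjusted over the list alone; 0.00013, and 0.11) and the DNA repair list (EXO1, 0.59; 2 adjusted over the list alone; 0.0042, and 0.25). The lists of NRF2 targets (median 0.08, adjusted p = 0.037, and 0.36 with an estimated correlation) and hypoxia (median 0.11, 0.032, and 0.50) passed with no member past the test by either count. Blocked by replicate the count was 247. It was 57, 86 and 31 without untreated 72 h replicate 1, 2 or 3 and 317, 34 and 42 without Pu5- 72 h replicate 1, 2 or 3. The calls of CCNE2 (adjusted p = 0.093, without untreated 72 h replicate 3), CACNA2D4 (0.075) and PPP1R10 (0.32, both without Pu5- 72 h replicate 2) ended. So did those of the p53 (0.080), DNA repair (0.091), hypoxia (0.086) and NRF2 (0.21) lists without 1 array or another.

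Over the mean of the times Pu5- raised 32 genes and lowered 14 (122 and 44 when blocked by replicate). The largest rises were in CCNE2 (0.62 ± 0.14, adjusted p = 0.035), LMNB1, which encodes lamin B1 (0.47), CLSPN, an adaptor of the replication checkpoint (0.43), CD160 (0.41), PRPS1 (0.35), TCF19 (0.35), DOCK9 (0.34), the tubulin TUBA1A (0.33), GPD2 (0.33) and CDC6 (0.32). Besides SELENOW (-0.81), GPX1 (-0.75) and SELENOH (-0.66), the falls by the rule were CLEC12B (-0.49), UBE2V1 (-0.31), CD38 (-0.30), KIF20A (-0.28), CDC20 (-0.25), PSRC1 (-0.24) and the centromere protein CENPE (-0.24). Sterol synthesis genes were higher in 19 of 19 (median 0.19, adjusted p = 5.5e-11, and 0.20 with an estimated correlation), with none past the test over all genes and 8 adjusted over the list alone. Cell cycle genes had 3 rises and 1 fall (9 and 3 adjusted over the list alone; adjusted p = 0.012, and 0.33 with an estimated correlation). Lists without a member past the test over all genes were monocyte markers (adjusted p = 0.022, and 0.33 with an estimated correlation; 2 rose adjusted over the list alone), the stress response (0.022, and 0.33; 4 rose and 1 fell), NRF2 targets (0.0011, and 0.20; 2 and 1) and DNA repair (0.00028, and 0.20; 2 rose). At 48 h the heat shock (median 0.11, adjusted p = 0.0019, and 0.030 with an estimated correlation), monocyte (median 0.04, 0.046, and 0.62) and sterol synthesis lists (median 0.15, 1.7e-07, and 0.51) passed, with 1 monocyte marker adjusted over the list alone. At 24 h the cell cycle (median 0.07, adjusted p = 0.011, and 0.38 with an estimated correlation), interferon (0.07, 0.011, and 0.13), NRF2 (0.11, 0.034, and 0.38) and DNA repair lists (0.07, 0.014, and 0.38) passed with no member past the test by either count. Each call ended without Pu5- 24 h replicate 1 (adjusted p up to 0.67). The 48 h heat shock call ended without Pu5- 48 h replicate 1 (0.25) and the 48 h monocyte call without untreated 48 h replicate 2 (0.81). Of the 20 named calls of the mean contrast 10 ended without 1 array or another, CCNE2 among them (0.12 without untreated 72 h replicate 3), as did the calls of the cell cycle (0.064), monocyte (0.14) and stress response lists (0.078). The count of 46 moved to 27 and 25 without untreated 24 h replicate 1 or 3, 30 without untreated 48 h replicate 2, and 19 without untreated 72 h replicate 3. It moved to 20 without Pu5- 24 h replicate 1, 18 without Pu5- 48 h replicate 2, 70 and 20 without Pu5- 72 h replicate 1 or 2, and 3 without all 72 h arrays.

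**Figure D5:**
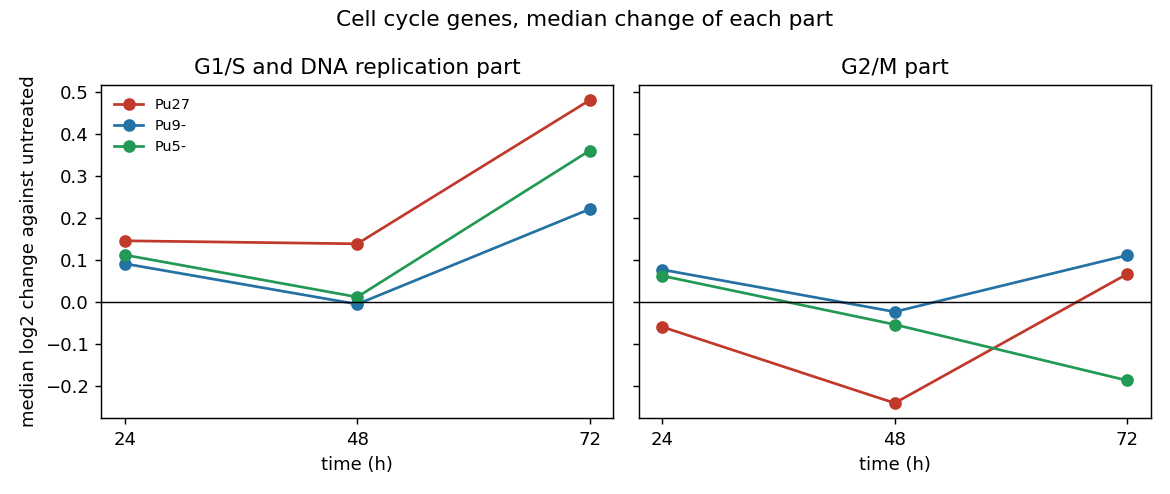
Median log2 change against untreated cells of the same time (vertical axis) of the 15 G1/S and 16 G2/M genes of the cell cycle list, against time (h), with a line for each oligonucleotide. The G1/S median at 72 h is 0.48 with Pu27, 0.22 with Pu9- and 0.36 with Pu5-, and the G2/M median is -0.24 with Pu27 at 48 h and -0.19 with Pu5- at 72 h.

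Pu27 and Pu9-, which lies within it, differed in 251 genes over the mean of the times (187 higher and 64 lower with Pu27). With Pu27 CCNE2 was 1.15 ± 0.14 higher (adjusted p = 3.6e-06), CX3CR1 0.95 ± 0.15, CXCL8 0.93 ± 0.22, ITGAM 0.86 ± 0.10 (1.1e-06) and GPR18 0.85 ± 0.18. Lower were PIF1 (-0.54), KIF20A (-0.53), CILK1 (-0.49), CIPC (-0.40) and DLGAP5 (-0.39). At 48 h 12 genes differed: CCNE2 (1.27), CCDC80 (1.10), ITGAM (1.08), the chemoattractant receptor FPR2 (0.80), SUCNR1 (0.75) and LRRC7 (0.60, a dim gene with a mean log2 of 3.88) were higher with Pu27. KIF20A (-0.73), CDC20 (-0.50), DLGAP5, CENPE, CDCA2 and AURKA were lower. At 72 h 273 genes differed, among them HLA-DRA, 0.91 higher with Pu27 (0.65 to 1.17, adjusted p = 0.00011). MYC target genes were lower with Pu27 than with Pu9- at 72 h in 29 of 38 (median -0.16, adjusted p = 2.7e-07, and 0.045 with an estimated correlation; 2 fell, and 1 rose and 3 fell adjusted over the list alone). So were G-quadruplex helicases and binding proteins in 13 of 19 (median -0.08, 0.0040, and 0.043 with an estimated correlation; 2 fell, and 1 rose and 4 fell adjusted over the list alone). The ACTB difference at 72 h was 2.24 with Pu27 and 2.10 with Pu9-, 1.27 SD apart. With it as a covariate the count at 72 h was 297, the MYC target (adjusted p = 2.6e-05) and G-quadruplex lists (0.0070) kept their calls at 72 h, and the NF-kB list at 48 h (0.062) and the ribosomal protein list of the mean (0.17) lost theirs. At 24 h limma called 0 genes, with 898 at an unadjusted p under 0.05, and 90.6% of genes had a 95% interval of the difference within 0.5 of 0. Blocked by replicate the count was 48 at 48 h, 599 at 72 h and 544 for the mean, and in a fit of the compared groups only it was 5, 15 and 166. Another split of the arrays of 72 h gave 199 genes.

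At single times, other lists were higher with Pu27 than with Pu9- but lost the call with an estimated correlation. At 72 h they were cell cycle genes (5 higher over all genes, 10 higher and 2 lower adjusted over the list alone; adjusted p = 0.0025, and 0.28 with an estimated correlation), monocyte markers (5, also 5; 0.0018, and 0.28) and DNA repair genes (2 higher and 1 lower, 8 and 1; 0.043, and 0.51). At 48 h they were NF-kB genes (0.034, and 0.56 with an estimated correlation) and monocyte markers (0.00038, and 0.35), and at 24 h NF-kB genes (0.012, and 0.51). For the mean, MYC target genes (median -0.09, adjusted p = 3.5e-07), interferon genes (median 0.06, 0.0055) and G-quadruplex helicases and binding proteins (median -0.06, 0.0055) kept the call, each with an adjusted p of 0.047 with an estimated correlation. The NF-kB, monocyte and DNA repair lists, higher with Pu27, and the ribosomal protein list, lower with Pu27, did not keep it (0.32, 0.19, 0.44 and 0.44 with an estimated correlation). The count of 273 at 72 h moved to 729, 45 and 97 without Pu9- 72 h replicate 1, 2 or 3 and to 60 and 174 without Pu27 72 h replicate 1 or 2. That of 12 at 48 h moved to 4 without Pu9- 48 h replicate 2 or 3 and to 2 and 7 without Pu27 48 h replicate 1 or 2. That of 0 at 24 h moved to 1 without Pu27 24 h replicate 2. The 251 of the mean moved to 154 without Pu9- 24 h replicate 3, 156 without Pu9- 48 h replicate 2, and 464 and 154 without Pu9- 72 h replicate 1 or 2. It moved to 140 without Pu27 24 h replicate 1, 164 and 165 without Pu27 48 h replicate 1 or 2, and 16 without all 72 h arrays. The call of CXCL8 ended without 1 array. Of the lists, calls that ended without 1 array or another were NF-kB at 24 h (adjusted p up to 0.68) and 48 h (0.12), monocyte markers at 48 h (0.10), cell cycle (0.066) and DNA repair (0.25) at 72 h, and DNA repair (0.14) and ribosomal proteins (0.17) for the mean.

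Pu27 and Pu5- differed in 45 genes over the mean of the times (43 higher and 2 lower with Pu27). CCNE2 was 0.71 ± 0.14 higher (adjusted p = 0.0094), ITGAM 0.70 ± 0.10 (0.00023), DNAJC5B 0.61 ± 0.07 (1.0e-05), SUCNR1 0.52 ± 0.09 and CD160 0.52 ± 0.08. CILK1 was lower (-0.47 ± 0.10, 0.028). At 72 h 45 genes differed, and HLA-DRA was 0.89 higher (adjusted p = 0.0004) and ITGAM 0.85 higher (0.013) with Pu27. All 16 G2/M genes were lower with Pu27 at 48 h (median -0.21, 0 past the test over all genes, 4 adjusted over the list alone, adjusted p = 8.4e-07 with an estimated correlation) and higher at 72 h (median 0.27, 2 and 13, 1.3e-05). At 72 h cell cycle genes (29 of 31 higher; 2 rose, 14 adjusted over the list alone; adjusted p = 6.3e-12, and 0.0085 with an estimated correlation) and MYC target genes (32 of 38 lower; 1 fell, 2 adjusted over the list alone; 4.3e-08, and 0.034) kept their calls. Interferon genes (0.0498, and 0.13) and monocyte markers (0.0033, and 0.33) did not. The ACTB difference at 72 h was 2.24 with Pu27 and 2.04 with Pu5-, 1.90 SD apart. With it as a covariate the count at 72 h was 41, and the cell cycle (adjusted p = 4.8e-11) and MYC target lists (7.5e-05) kept their calls. The MYC target list at 48 h (0.056) and the ribosomal protein list of the mean (0.17) lost theirs. For the mean, MYC target genes (median -0.08, adjusted p = 2.0e-07, and 0.042 with an estimated correlation) and G-quadruplex helicases and binding proteins (median -0.06, 0.0025, and 0.020) kept it. The interferon, NF-kB, monocyte and ribosomal protein lists did not (0.12 to 0.50 with an estimated correlation). At 48 h CCDC81 (0.51), a dim gene with a mean log2 of 3.60, CENPE (-0.44) and KIF20A (-0.67) differed. At that time 7 lists had an adjusted p of 0.031 to 0.036, with 0.15 to 0.54 with an estimated correlation. At 24 h limma called 0 genes, with 726 at an unadjusted p under 0.05, and 91.1% had an interval within 0.5 of 0. In the blocked fit 25 genes differed at 48 h, 118 at 72 h and 119 for the mean (0, 3 and 17 with the compared groups only), and the interferon list also passed (adjusted p = 0.048). All 7 lists at 48 h, the interferon (0.21) and monocyte lists (0.074) at 72 h, and the interferon (0.13), NF-kB (0.16) and ribosomal protein lists (0.16) of the mean lost their calls without 1 array or another (at 48 h up to 0.53). The 3 calls at 48 h became 0 and 1 without Pu5- 48 h replicate 1 or 2 and 1 without Pu27 48 h replicate 1. The 45 at 72 h became 19 and 13 without Pu5- 72 h replicate 2 or 3 and 21, 14 and 69 without Pu27 72 h replicate 1, 2 or 3. The 45 of the mean became 70 without Pu5- 24 h replicate 1, 27 without Pu5- 72 h replicate 3, 29 without Pu27 24 h replicate 1, which also ended the call of CILK1 (0.099), and 11 without all 72 h arrays.

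Between Pu9- and Pu5- limma called few genes: 0 for the mean (458 at an unadjusted p under 0.05), 0 at 24 h (732) and 0 at 48 h (161). The 95% interval of the difference lay within 0.5 of 0 on the log2 scale for 99.8% of the genes for the mean. It did so for 90.5%, 95.6% and 91.4% at 24, 48 and 72 h. At 72 h 9 genes differed, all higher with Pu9-: KIF20A by 0.72 (adjusted p = 0.00036), DLGAP5 by 0.62, KNSTRN by 0.52, HMMR by 0.52, CENPE by 0.48, CDC20 by 0.48, CCNB1 by 0.45, NEK2 by 0.44 and DEPDC1B by 0.41. At that time all 16 G2/M genes were higher with Pu9- (median 0.26, 2 past the test, 8 adjusted over the list alone, adjusted p = 4.1e-08 with an estimated correlation). All 15 G1/S genes were lower (median -0.16, 0 past the test, 2 adjusted over the list alone, 0.016). The whole cell cycle list had a median of 0.08 with 2 rises (7 and 3 falls adjusted over the list alone; adjusted p = 0.012, and 0.53 with an estimated correlation). The heat shock (median 0.07, 0.022) and histone lists (median 0.19, 0.012) passed at 72 h and the sterol synthesis list for the mean (median -0.06, 0.042), each with no member past the test by either count. They had 0.16, 0.16 and 0.78 with an estimated correlation. HLA-DRA at 72 h differed by -0.02 (-0.28 to 0.24) and ITGAM by 0.01 (-0.33 to 0.34). The count at 72 h was 0 in a fit of the compared groups only, and another split of those arrays gave 414 genes. It was 3 and 4 without Pu5- 72 h replicate 1 or 3 and 30 without Pu9- 72 h replicate 1, and that of the mean was 1 without Pu5- 24 h replicate 2. The calls of the 4 fixed lists ended without 1 array or another (adjusted p up to 0.26 for cell cycle, 0.39 for heat shock, 0.35 for histones and 0.90 for sterol synthesis). With a replicate block the sterol synthesis list passed at 72 h (0.014).

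Across all 18132 genes, which are not independent replicates, the mean changes of Pu9- and Pu5- correlated with r = 0.737, those of Pu27 and Pu5- with 0.633 and those of Pu27 and Pu9- with 0.535. Unchanged groups sharing the same untreated arrays gave 0.499, 0.499 and 0.501 in simulation. Part of the likeness may come from the shared controls, whose 3 arrays per time cannot be divided between the oligonucleotides. The covariances were 0.00575, 0.00634 and 0.00510 against 0.00272, 0.00272 and 0.00273 simulated, an excess of 0.00303, 0.00362 and 0.00237. At 72 h the excess was 0.0123, 0.0131 and 0.0119, and at 24 h 0.00078, 0.00258 and -0.00124. Effects at different times, which share no arrays, had median correlations of 0.133, 0.127 and 0.0895. At 72 h Pu27 shared 59 rises with Pu5-, where independent lists would share 2.0 and equally long lists of unchanged groups with the same untreated arrays 22.1 in simulation. It shared 44 with Pu9- (2.41 and 25.7), and Pu9- and Pu5- shared 29 (0.308 and 6.94). Shared falls numbered 47 (1.57 and 19.3), 50 (1.97 and 23.6) and 34 (0.370 and 7.89). All 3 oligonucleotides shared 24 rises at 72 h (3.94 simulated, highest 8), among them CDC6 and MCM10, which act in starting DNA replication, CDC25A, DTL, the urokinase PLAU and PMAIP1, a pro-apoptotic relative of BCL2. They shared 27 falls (4.0 simulated, highest 9), among them SELENOH, CD44, AFF2, PPP1R10, RBMX, the ligase LIG4, CLEC12B and KLRF1. For the mean they shared the rises of PRPS1 and GPD2 (0.27 simulated, highest 2). The simulated values leave out real effects and the independent ones the shared arrays, so neither difference is a measure of a shared effect.

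The F test called few genes whose effect differs between 24, 48 and 72 h: 8 for Pu27, 1 for Pu9- and 8 for Pu5-. At an unadjusted p under 0.05 there were 1448, 988 and 876. Blocked by replicate the counts were 50, 5 and 19. Small counts from 3 arrays per group do not show steady effects. Between times, changes of 1 oligonucleotide correlated with r of 0.185 to 0.307, 0.029 to 0.217 and 0.095 to 0.242. HLA-DRA, SELENOW and CLEC2A led for Pu27, SELENOW for Pu9-, and SELENOW, CLEC2A and MCM10 for Pu5- (values below). Without untreated 72 h replicate 3 the Pu27 count was 5, and without Pu9- 72 h replicate 1 the Pu9- count was 200. The Pu5- count of 8 moved without each of 10 single arrays. It was 4 and 3 without untreated 24 h replicate 1 or 3, 3, 1 and 4 without untreated 72 h replicate 1, 2 or 3, 2 and 1 without Pu5- 24 h replicate 1 or 3, and 19, 1 and 1 without Pu5- 72 h replicate 1, 2 or 3.

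In untreated cells 5192 genes differed between 24 h and 0 h (2537 higher, 2655 lower), 939 between 48 h and 0 h and 2828 between 72 h and 0 h (1380 and 1448). At 24 h MYC target genes rose, 30 of 38 (31 adjusted over the list alone; median 0.55, adjusted p = 1.5e-14, and 0.0014 with an estimated correlation). So did 11 of 14 heat shock protein genes (also 11; median 0.66, 3.4e-10, and 2.1e-05). CCL2 rose by 5.26 (adjusted p = 1.1e-10) and the calgranulin gene S100A9 by 3.07. Sterol synthesis genes were lower in 19 of 19 with 17 falls by either count (median -0.80, adjusted p = 8.2e-10, and 0.18 with an estimated correlation). MSMO1 fell by 1.63 and DHCR7 by 1.23. Cell cycle genes (17 rises and 2 falls, 18 and 3 adjusted over the list alone; median 0.38, adjusted p = 7.3e-06) and NRF2 targets (8 rises by either count; median 0.34, 0.00041) had 0.087 each with an estimated correlation. The hypoxia list (4 rises, 11 falls; median -0.28, 0.039, and 0.59) lost its call without untreated 0 h replicate 2 (0.15).

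At 72 h the untreated cells were lower than at 0 h in the lists of hypoxia and glycolysis, MYC target genes and the immediate early and MAPK response, among others. Hypoxia and glycolysis genes had 17 falls in 22 by either count (median -0.71, adjusted p = 1.1e-16, and 0.0089 with an estimated correlation). They were led by PFKFB4, a regulator of glycolysis (-1.97 ± 0.30), the aldolase ALDOC (-1.53), BNIP3 (-1.42) and P4HA1 (-1.17). MYC target genes had 20 falls (21 adjusted over the list alone; median -0.27, 3.8e-08, and 0.022 with an estimated correlation). The largest were in the transferrin receptor TFRC (-1.33), LDHA (-0.80), MRTO4 (-0.76) and NIP7 (-0.76). MAPK response genes had 10 falls and 1 rise (12 and 1 adjusted over the list alone; median -0.31, 3.7e-06, and 0.016 with an estimated correlation). DUSP6, an ERK phosphatase (-2.02 ± 0.25, 1.8e-06), and SPRY2 (-1.54) fell, while SPRY4 rose by 1.12. Cell cycle genes had 13 falls (16 adjusted over the list alone; median -0.31, 2.4e-05, and 0.056 with an estimated correlation) and metallothioneins 5 of 8 (also 5; median -0.42, 0.00016, and 0.047). Granule enzymes had 3 falls in 9 (4; median -0.23, 0.018, and 0.049), RNASE2 (-1.16) among them, and heat shock proteins 4 in 14 (5; median -0.18, 0.018, and 0.049; 0.070 without untreated 0 h replicate 2). The other falls by the rule were ETV5 (-1.69 ± 0.19, 5.1e-07), DPCD (-1.39), the pyruvate kinase PKM (-1.38) and LSP1 (-1.27). The rises were CLK1, a kinase of splicing factors (1.94 ± 0.25, 3.2e-06), the lectin-like CLEC2D (1.76 ± 0.20, 4.7e-07), RSRP1 (1.49), SYCP2 (1.49), ALDH8A1 (1.37), GOLGA8A (1.24), CCPG1 (1.22), GKAP1 (1.21), KLHL24 (1.21) and AHSA2P (1.21). The count of 2828 was 1561 without untreated 72 h replicate 2.

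At 48 h against 0 h the lists that kept their calls were cell cycle genes (8 rises, 14 adjusted over the list alone; median 0.31, adjusted p = 1.2e-08, and 0.025 with an estimated correlation), hypoxia and glycolysis (11 falls, 15; median -0.31, 3.0e-13, and 0.025) and MAPK response (2 falls, 4; median -0.23, 9.5e-05, and 0.047). The sterol synthesis (median -0.33), MYC target (0.18), DNA repair (0.22), metallothionein (-0.25), NF-kB (-0.21), histone (-0.26), stress response (-0.09), heat shock (0.08) and G-quadruplex helicase lists (0.18) had an adjusted p from 1.8e-06 to 0.044, and 0.077 to 0.18 with an estimated correlation. The last 3 of these ended without 1 array, with an adjusted p of 0.63, 0.19 and 0.11. The count of 939 was 624 and 584 without untreated 0 h replicate 2 or 3, and 575 and 444 without untreated 48 h replicate 1 or 2.

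Of the 29 lists, 16 passed in none of the 12 comparisons of an oligonucleotide with untreated cells, with a lowest adjusted p of 0.057 and medians between -0.17 and 0.21. These were apoptosis regulators, G-quadruplex helicases and binding proteins, scavenger and uptake receptors, autophagy and lysosome, histones, MAPK response, ribosomal proteins, oxidative phosphorylation, nucleic acid sensing, genes with a G-quadruplex motif described in their promoter, granule enzymes, and the markers of epithelial, erythroid, T, fibroblast and B cells. Single members passed, such as the apoptosis regulators BCL2A1 (0.66, adjusted p = 0.0011) and PMAIP1 (0.25) and the DNA sensor AIM2 (0.71, 0.0025) with Pu27 over the mean of the times.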

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

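Chosen after the result was seen were the tests of 1 array deciding a result, of RNA quality as the whole cause, of a change in cell cycle stage, of mislabelled untreated arrays, of splits with the mean effect removed, of 1 scaling factor, of SELENOW alone and of 100 splits that part every replicate number. For some genes the effect of an oligonucleotide differed between 24, 48 and 72 h by limma's moderated F test. With Pu27 these were HLA-DRA (adjusted p = 0.0042; log2 changes 0.03, 0.86 and 1.20), SELENOW (0.0042; -1.23, -0.57 and -0.41), CLEC2A (0.0042; 0.25, 0.08 and -0.59), LIG4 (0.0045; 0.10, -0.07 and -0.97), HESX1, a dim gene with a mean log2 of 4.06 (0.0059; 0.54, -0.16 and -0.63), BPI, a bactericidal granule protein (0.0115; -0.13, 0.54 and 1.21), MCM10 (0.0123; 0.12, 0.18 and 0.70) and CCDC80 (0.0292; 0.52, 1.12 and 1.78). With Pu9- SELENOW alone differed (0.000165; -1.38, -0.66 and -0.34). With Pu5- they were SELENOW (0.0019; -1.31, -0.77 and -0.36), CLEC2A (0.0197; 0.31, 0.12 and -0.47), MCM10 (0.0197; 0.06, 0.07 and 0.63), ARHGEF39 (0.0197; 0.15, -0.12 and -0.98), HESX1 (0.0239; 0.43, 0.10 and -0.62), ASPM of the mitotic spindle (0.0239; 0.07, -0.08 and -0.76), KIF20A (0.0472; -0.03, -0.09 and -0.73) and HMMR (0.0496; 0.10, -0.13 and -0.58). Of 100 splits that move arrays between treated and untreated, 11, 19 and 8 gave at least as many such genes as Pu27, Pu9- and Pu5- did (8, 1 and 8; 50, 5 and 19 with a replicate block), with 610, 21 and 37 the highest others. Of 100 that part every replicate number, 23, 31 and 11 gave as many, with 443, 34 and 46 the highest others. Both sets decide nothing, since moving arrays at single times turns a steady effect into one that differs between times. With the mean effect of the oligonucleotide first taken off its arrays, 1, 3 and 1 of 100 splits gave as many (highest others 1, 2 and 5), and 3, 5 and 1 of 100 that part every replicate number (8, 1 and 5). Chance is thereby argued against for Pu27 and Pu5- and left open for Pu9-. Taking off an estimated effect also takes some chance differences out of the other splits and none out of the real one, so these shares may be somewhat low.

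Among the control probe sets, which no comparison uses, every Pu27 array at 72 h had a larger ACTB 3' minus 5' difference than every untreated array of that time, by 0.19 on the log2 scale. This was 1 of 45 such comparisons, each of which has a chance of 5%, and the smallest exact two-sided p for 3 arrays against 3 is 0.1.

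SELENOW, SELENOH and GPX1 were lower with all 3 oligonucleotides. The signal of a single probe set is argued against by the other probe sets of GPX1 and SELENOH (median change -0.59), but SELENOW has 0 other probe sets and stays open. A general loss of selenoprotein mRNA is argued against by the 14 other selenoprotein genes with a mean log2 of at least 6 (median -0.022, SD 0.114, against a mean of -0.66 for the 3 genes). RNA quality as the whole cause is argued against by the 9 mean changes, all past the test and the smallest -0.52 with the ACTB difference as a covariate, and it stays open as a part of the Pu27 values at 72 h, where that difference was 1.79 SD. Also open are a limited supply of selenium as a candidate explanation, on which MSRB1 (-0.097, SE 0.083) does not decide, and an effect of any oligonucleotide, untested as the design held no control oligonucleotide.

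Genes of G1/S were higher with Pu27 at 72 h (median 0.48). In untreated cells all 15 were lower at 72 h than at 0 h (median -0.40, 10 past the test). The contrast need not be a rise above the 0 h level, which was not tested. Against a single array deciding the contrast stands a lowest median of 0.44 without 1 of the 6 arrays. Against RNA quality as the whole cause stands a median of 0.53 with the ACTB covariate (12 of 15 genes past the test in place of 13). As a part it stays open (ACTB difference 1.79 SD, GAPDH 0.972 SD). As a hypothesis, cell cycle stage (not measured) may have changed. The G1/S median exceeded the G2/M median by 0.41, but the parts were set apart after seeing the values, so this is no test.

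Untreated cells at 24 h stood apart from those at 0 h and 72 h. RNA quality is argued against by ACTB and GAPDH differences of at most 0.718 SD, and mislabelled untreated arrays by the oligonucleotide arrays of 24 h, of which 9 of 9 lay nearest to the untreated 24 h mean. Against 1 scaling factor as the whole cause, 5154 genes against 0 h and 6432 against 72 h still differed at the common offset, of those from -1 to 1, that left the fewest. Array scaling as a part stays open, since the hybridisation spike-in probe sets differed by -0.60 from 72 h and 0.09 from 0 h, with an SD within groups of 0.47. Time in culture, which the design names, remains a biological explanation and was not tested apart from these.

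Splits of the arrays bear on each count. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were, at 24, 48 and 72 h, 12 and 2, 35 and 0, and 922 and 0 for Pu27. They were 3 and 0, 3 and 1, and 174 and 211 for Pu9-, and 3 and 3, 3 and 0, and 141 and 1 for Pu5-. For untreated cells against 0 h they were 5192 and 2, 939 and 102, and 2828 and 12. Between oligonucleotides they were 0 and 0, 12 and 0, and 273 and 199 for Pu27 and Pu9-. For Pu27 and Pu5- they were 0 and 1, 3 and 0, and 45 and 0, and for Pu9- and Pu5- 0 and 1, 0 and 0, and 9 and 414. As many genes came, the real split included, from 2 splits for Pu9- at 72 h and Pu5- at 24 h, from 3 for Pu9- against Pu5- at 72 h, from all 10 where the real count was 0, and otherwise from 1. The 414 genes of Pu9- against Pu5- at 72 h, several times the real 9, point to a structure of the samples. They and the 211 of Pu9- at 72 h came from splits that set replicate 1 of Pu9- with replicates 1 and 2 of the other group. With a replicate block the counts were 12 and 459. Each comparison has 4 splits that part every replicate number, and the highest other among them was 0 for both of these, and 3 for Pu27 against Pu9- at 72 h. For the means over times the real split alone, of 100, gave as many genes for Pu27 (722, highest other 210), Pu9- (16 and 6), Pu5- (46 and 9), Pu27 against Pu9- (251 and 5) and Pu27 against Pu5- (45 and 7). Since same-numbered replicates were alike, 100 splits that part every replicate number were drawn as well. In these the highest others were 497, 18, 33, 179 and 23 in the same order. As many genes came from 2 splits for Pu9- and 1 for the others. Both sets argue against chance. Chance stays open for Pu9- against Pu5-, where all 100 of each set gave at least the real 0 (highest others 2 and 1).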

How the results depend on the processing

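Except for the ACTB covariate and the means without 72 h, the alternatives were planned. The 2 deposited tables did not differ in shared values, so the planned second source was not run, and MYC has no other probe set. The prior of limma does not enter camera, so the trend and robust setting gave no values for lists, and the means without 72 h were not run for them. Signal over background limits dim genes: array medians were 5.82 to 5.94 and background probes 3.06 to 3.25. A left-out array leaves 2 in its group. Of the values of named genes under alternatives, 2352 kept direction and call, 534 kept the direction without the call and 0 reversed. Of those of lists 14008 stayed on the same side of the test, 228 gained and 379 lost a call, and 1 reversed. The list sterol and fatty acid synthesis, Pu27 against Pu9-, 72 h, not called with all arrays, was called in the opposite direction without Pu9- 72 h replicate 1. Its adjusted p ranged from 0.0385 there to 0.842 over the settings that leave out arrays. For MYC 526 values stayed on the same side of the test and 11 lost the call. Among values not past the test with either choice, 46 of MYC and 1208 of lists changed sign, and for counts 404 were within 1.5 times and 220 were not. Except where fewer samples, fewer genes or a larger number of tested probe sets is the construction of the setting, the cause was not tested.

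With a replicate block (paired replicate numbers) the counts were 37 and 80 for Pu27 at 24 and 48 h, 459 and 58 for Pu9- at 72 h and the mean, 247 and 166 for Pu5- at 72 h and the mean, and 1457 for untreated 48 h against 0 h. They were 1, 48, 599 and 544 for Pu27 against Pu9- at 24, 48, 72 h and the mean, 25, 118 and 119 for Pu27 against Pu5- at 48, 72 h and the mean, and 50, 5 and 19 for the effects that differ between times with Pu27, Pu9- and Pu5-. The block also called the DNA repair list for the mean of Pu9- (adjusted p = 0.026) and granule enzymes for untreated 48 h against 0 h (0.031), and ended no list call.

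In a fit of the compared groups only, with fewer samples, the counts were 4, 2 and 335 for Pu27 at 24, 48 and 72 h, 1, 0, 0 and 5 for Pu9- at the 3 times and the mean, 0, 15 and 22 for Pu5- at 48, 72 h and the mean, and 53 and 1727 for untreated 48 and 72 h. They were 5, 15 and 166 for Pu27 against Pu9- at 48, 72 h and the mean, 0, 3 and 17 for Pu27 against Pu5-, 0 for Pu9- against Pu5- at 72 h and 2 for the Pu5- effects that differ between times. MYC in untreated cells at 48 h was -0.35 (adjusted p = 0.268). Without dim genes the counts were 277 and 26 for Pu9- at 72 h and the mean, 73 for the mean of Pu5- and 6 for Pu27 against Pu5- at 48 h. With a trend and robust prior they were 25 for the mean of Pu9-, 19 for Pu27 against Pu9- and 7 for Pu27 against Pu5- at 48 h, and 18 for the Pu27 effects that differ between times. With the mean of a gene's probe sets they were 7 for Pu27 against Pu5- at 48 h, and 22 and 3 for the Pu27 and Pu9- effects that differ between times. Over every probe set they were 1934 and 1178 for Pu27 at 72 h and the mean, 5, 5 and 374 for Pu9- at the 3 times, 5 and 7 for Pu5- at 24 and 48 h, and 12918, 1904 and 6163 for untreated cells. They were 519 and 381 for Pu27 against Pu9- at 72 h and the mean, 74 for Pu27 against Pu5- at 72 h, 1 and 1 for Pu9- against Pu5- at 48 h and the mean, and 14 for the Pu27 effects that differ between times, with MYC at 48 h -0.35 (0.053). With arrays shifted to a common median they were 8 for the mean of Pu9-, 1 for Pu27 against Pu5- at 48 h and 5 for Pu9- against Pu5- at 72 h, with MYC at 48 h -0.34 (0.056). With the ACTB covariate MYC at 48 h was -0.33 (0.069), and 9 list calls were gained and 11 lost. Without 72 h the means had 78 genes for Pu27, 3 for Pu9-, 3 for Pu5-, 16 for Pu27 against Pu9- and 11 for Pu27 against Pu5-. Correlations of the mean effects were 0.542, 0.662 and 0.781 over bright genes for Pu27 with Pu9-, Pu27 with Pu5- and Pu9- with Pu5-, and 0.0895, 0.127 and 0.133 between different times.

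Leaving out single arrays or a replicate number gave ranges of 1 to 25, 0 to 35, 68 to 999 and 114 to 752 for Pu27 at 24, 48, 72 h and the mean. In the same order they were 1 to 3, 1 to 7, 0 to 1367 and 3 to 359 for Pu9- and 3 to 4, 2 to 4, 1 to 556 and 3 to 107 for Pu5-. For untreated cells at 48 and 72 h they were 59 to 1330 and 503 to 3127. Between oligonucleotides they were 0 to 1, 0 to 17, 1 to 729 and 10 to 464 for Pu27 against Pu9-, 0 to 2, 0 to 70 and 0 to 70 for Pu27 against Pu5- at 48, 72 h and the mean, and 0 to 30 and 0 to 1 for Pu9- against Pu5- at 72 h and the mean. They were 0 to 60, 0 to 317 and 0 to 42 for the effects that differ between times. For untreated 24 h the range was 3701 to 4761. MYC ranged from -0.54 to -0.24 at 48 h and -0.64 to -0.47 at 72 h in untreated cells.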

Other observations

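With Pu27 at 72 h single genes passed the test in lists that did not pass as a whole, and these genes were picked after their values were seen. Among apoptosis regulators BCL2A1, an inhibitor of apoptosis, rose by 1.02 and PMAIP1, which promotes it, by 0.50. Among genes of the MAPK response the ERK pathway inhibitor SPRY2 rose by 0.84 and the phosphatase gene DUSP5 by 0.56. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.53 in the p53 list. The lysosomal membrane proteins GPNMB and LAMP1 rose by 0.44 and 0.34, and the G-quadruplex helicase DHX9 fell by 0.24. Of granule enzyme genes RNASE2 rose by 0.51.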
